A study of Homo sapiens with 10 samples.

How the data were processed

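Total RNA, polysomal RNA and post-polysomal RNA of MCF10AT cells with an empty MSCV vector or with YB-1 were measured on 10 Affymetrix Human Exon 1.0 ST arrays. Per the labels' protocols, monolayer cultures were lysed with a nonionic detergent in the presence of cycloheximide, which holds ribosomes on mRNA, the fractions were taken from sucrose gradients, ribosomal RNA was removed, and sense-strand target was labelled across whole transcripts. The number of arrays limits the precision, and signal over background limits what can be seen of dim genes.

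The deposited gene-level table and the deposited exon-level table both hold RMA intensities, per the labels and the submitters' processing notes, and their values are on a linear scale. The RMA version is not given in the sources used here. Quantiles of the deposited intensities differed between arrays, and the normalization within RMA is not given in the sources used here. The gene-level table has 17020 rows on HG-U133 Plus 2 identifiers with full gene names. The deposited map, per its file header, gives start and stop positions on hg16 (NCBI 34) and assigns exon-level probesets to those rows. The exon-level table has 283146 probesets, with a median of 13 per gene tested.

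Values were turned to log2 with no pseudocount and no further scaling, although the plan had assumed values on the log2 scale as deposited. Of the rows, 1031 were left out as transcribed loci, clones or unnamed entries, and 15989 had a gene name. The plan spoke of gene symbols, but the table gives gene names, so the name defined a gene. Of the 264 names with more than 1 row, the row with the highest mean was used, which left 15719 genes. Symbols came from a reference table of GRCh38.p14, used for names only. YBX1 and ZEB2 were not analysed here. A gene that the rule below names is not reported here.

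The main test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes in their default form and a mean for each of 4 groups of 2 fraction arrays. The 8 arrays left 4 residual degrees of freedom. The 5 contrasts were YB-1 minus MSCV in polysomal RNA, the same in post-polysomal RNA, the difference of these (the interaction), and polysomal minus post-polysomal in each line. Benjamini-Hochberg adjusted p below 0.05 over all genes was the threshold, all tests were two-sided, and values are group differences ± SE. The total RNA arrays, 1 per line, stayed out of the fit and carry no p.

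Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 29 lists with at least 5 genes measured, within each contrast. The second form also refers its statistic to the 4 residual degrees of freedom, so a call can end without a high correlation. Between the fractions of YB-1 cells, immune cell genes had an estimated correlation of -0.005, and their camera adjusted p went from 0.0179 to 0.542. A total of 30 lists were written, and 863 of their 965 symbols matched a gene. In total RNA each list's median was placed among 10000 random lists of the same size matched on mean level in 20 bins, and a difference of at least 2-fold was counted. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 10 genes past the test with the largest difference in each direction of each contrast (or, where fewer than 5 pass, the 5 with the largest moderated t), up to 4 members with the largest moderated t from each list described, the 10 largest total RNA differences in each direction among genes above the median, and SNAI1, SNAI2, TWIST1, ZEB1, LEF1, TCF4, HIF1A, CDH1, CDH2, VIM and FN1 whatever their values. The text gives a part of these, and says where a gene was named outside the rule. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

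The alternatives left out the dimmest 25 percent of genes, centred each array on its median, quantile normalized the 8 arrays, took the mean over exon-level probesets or over a gene's rows, used only the 4 arrays of a contrast, used eBayes with trend and robust, added the replicate letter as a block, and left out each array in turn.

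The fit was tested on simulated data with the real genes, each at its mean over all fraction arrays and with its spread from the fit. The real differences between the groups and the separate spread of each group were not put in. In the polysomal comparison, over 15719 genes, 84 of 200 genes changed by 1 log2 unit and 199 of 200 changed by 2 were called. For the interaction over the same number of genes, 0 of 200 and 185 of 200 were called. With no change put in, both gave 0 calls. With changes of 1 and 2 log2 units put in, false calls numbered 2 and 8 in the polysomal comparison and 0 and 12 for the interaction. A list shifted by 0.5 in the polysomal comparison was called in 20 of 20 simulations, with 0 calls of other lists. Simulated genes did not move together, whereas the shifted list, ribosomal proteins, had an estimated correlation of 0.544 in the real arrays. The list simulation therefore does not check the camera p at the preset correlation for such lists.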

Results

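The arrays compared total RNA, polysomal RNA and post-polysomal RNA between MCF10AT cells carrying an empty MSCV vector and MCF10AT cells expressing YB-1. MCF10AT is an H-RAS-transformed derivative of the MCF10A breast epithelial line, and YB-1 is a cold shock domain protein that binds DNA and mRNA. The polysomal fraction of a sucrose gradient holds mRNA loaded with several ribosomes and counts as translationally active, and the post-polysomal fraction holds the lighter, inactive material. There were 10 Affymetrix Human Exon arrays: 1 total RNA array per line and 2 arrays, lettered A and B, for each fraction of each line. The labels call the lettered arrays biological replicates and say nothing more about separate cultures, so each p measures the spread between these arrays, which may be technical. Values were RMA intensities, given here as log2, and the tests covered 15719 named genes. The median gene stood at 4.90 in total RNA of MSCV cells and 4.78 in total RNA of YB-1 cells, at 4.42 to 4.48 in the polysomal arrays, and at 4.87, 5.18, 4.90 and 5.01 in the post-polysomal arrays (MSCV A, MSCV B, YB-1 A and YB-1 B). Replicates correlated across genes at r = 0.9924 (polysomal MSCV), 0.9899 (polysomal YB-1), 0.9866 (post-polysomal MSCV) and 0.9907 (post-polysomal YB-1). The replicate SD was 0.200, 0.222, 0.353 and 0.242 log2 units in that order, and the median of the differences per gene between post-polysomal MSCV arrays B and A was 0.272. The lower quartile of genes lay at 3.11 to 3.24 in the arrays, and no measure of background was used here, so a fold with a group near or under that level is not exact. The number of arrays limits the precision of every value below, and YBX1 itself was not analysed here, so its level did not check the labels.

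In total RNA, the first question was which transcripts differed between the lines before fractionation. Transcripts of the epithelial and basal programmes were far lower in YB-1 cells. RAB25, an epithelial vesicle-trafficking GTPase (row 218186_at, hg16 chromosome 1, 153252493 to 153257040), was 58.1-fold lower. KRT15 and KRT5, keratins of basal epithelium, were 49.7-fold and 37.4-fold lower, and ESRP1, the epithelial splicing regulator, was 39.4-fold lower. The matrix glycoprotein FN1 (fibronectin, row 212464_s_at, hg16 chromosome 2, 216428126 to 216502987) was 22.9-fold higher, the small proteoglycan DCN 14.8-fold higher and the matrix-binding protein SPARC 9.04-fold higher. RTN1, an endoplasmic reticulum protein, was 18.6-fold higher and SRGN, a secretory granule proteoglycan, 11.6-fold higher. Also lower were the transferase-family gene ART3 (51.5-fold), the carbonic anhydrase CA2 (46.4-fold), the epithelial integrin ITGB6 (35.2-fold) and the carnitine synthesis enzyme BBOX1 (33.95-fold). H3C3 (37.9-fold lower) and ANXA8 (32.01-fold lower) have near-identical copies in the genome, so their values are uncertain. ESRP1 (2.80), ART3 (2.64), ITGB6 (2.96), BBOX1 (2.98) and H3C3 (2.79) lay under the lower quartile in YB-1 cells, so their folds are not exact. Each line had 1 total RNA array, so these differences have no replicate check and no p.

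The gene lists placed those genes in groups. Of 39 measured epithelial junction and identity genes, 23 were at least 2-fold lower in total RNA of YB-1 cells and 0 were 2-fold higher. Their median difference was -1.81, below all of 10000 random lists matched on size and mean level (percentile 0). Of 25 basal and hemidesmosome genes, 19 were at least 2-fold lower, with a median of -1.67 and percentile 0. Of 43 mesenchymal and matrix genes, 10 were at least 2-fold higher and 3 were 2-fold lower, with a median of 0.14 and percentile 99.4. Immediate early genes, which encode rapidly induced transcription factors such as EGR1, had a median of -1.11 (percentile 0), and 11 of 22 were at least 2-fold lower. Targets of ATF4, the transcription factor of the integrated stress response, had a median of -0.49 (percentile 0). MAPK output genes had a median of -0.41 (percentile 0.07). DNA replication and mitosis genes lay higher, each with a median of 0.33 and percentile 100, and proteasome subunits had a median of 0.30 and percentile 99.9. Over all genes, 240 were at least 2-fold higher and 630 at least 2-fold lower (27.6% higher), around a median of -0.01. Centring each array on its own median moved that median to 0.12 and the counts to 330 and 506 (39.5% higher).

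**Figure D1:**
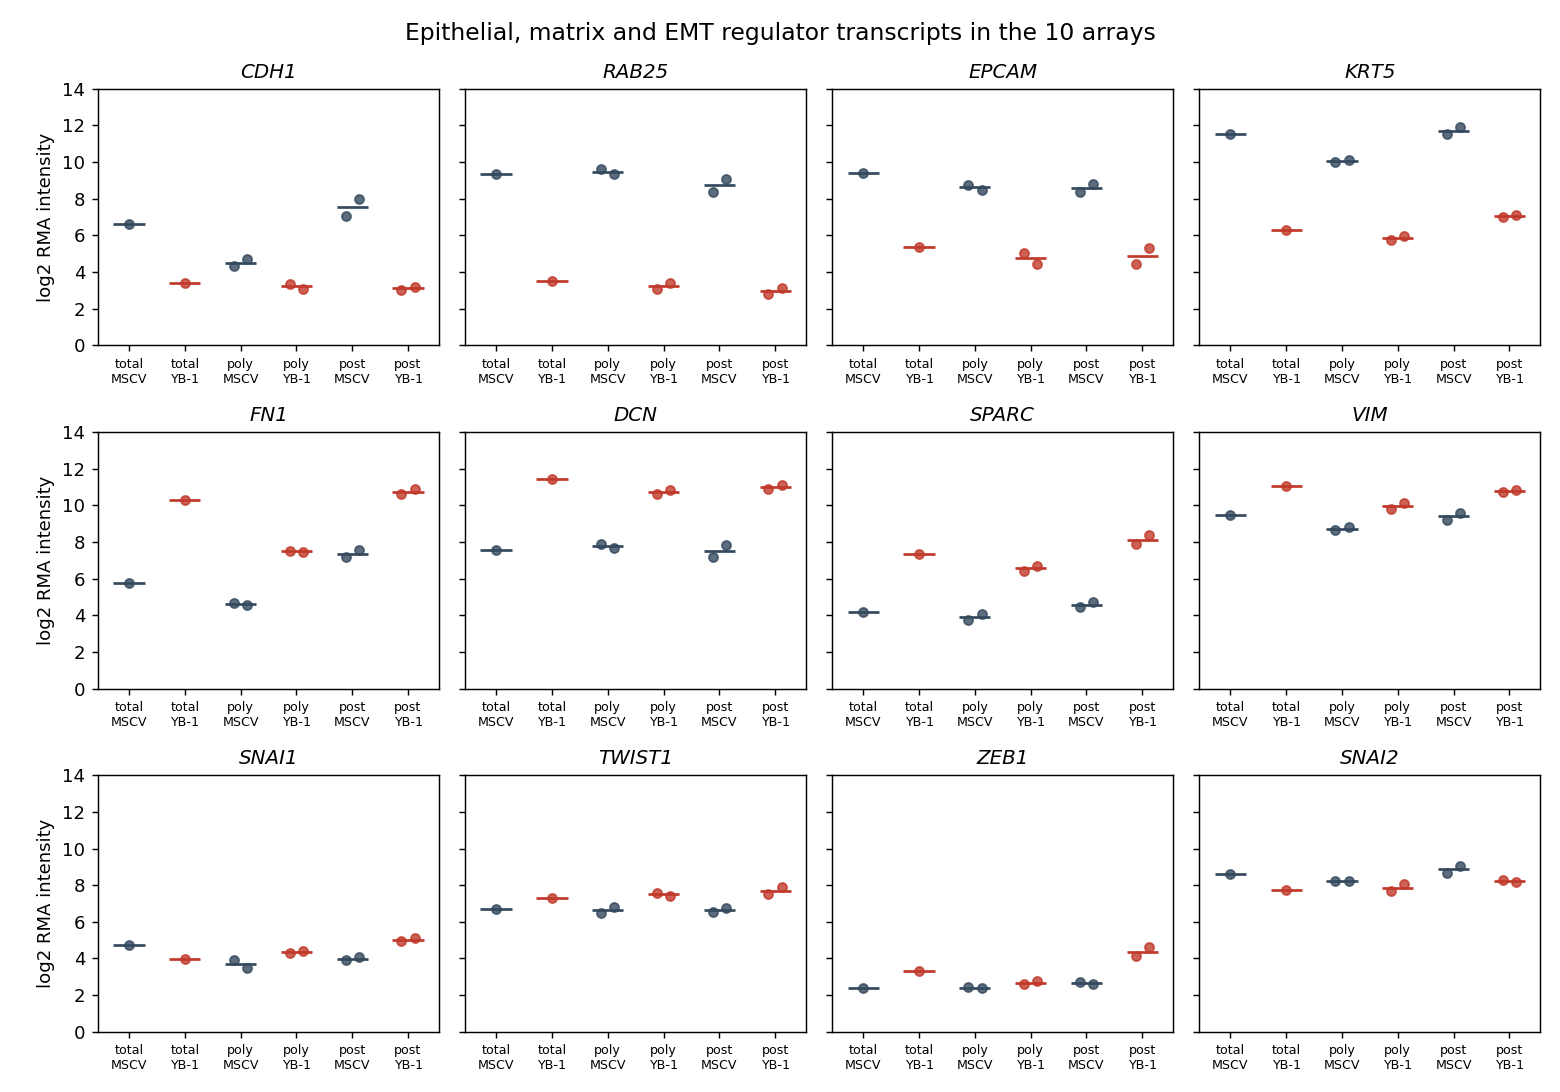
Log2 RMA intensity (y axis) of 12 epithelial, matrix and transcription factor genes in total, polysomal and post-polysomal RNA (x axis), for MSCV cells in blue and YB-1 cells in red. Each point is an array and each line a group mean, with 1 array per line in total RNA and 2 per line in each fraction, and RAB25 ran from 9.48 in polysomal MSCV RNA to 3.24 in polysomal YB-1 RNA.

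Between the lines, many epithelial and basal keratinocyte genes fell in polysomal RNA of YB-1 cells, and a smaller number of matrix genes rose. RAB25 fell 75.6-fold (log2 difference -6.24 ± 0.26 SE, n = 2 arrays per line, limma adjusted p = 8.28e-05). KRT15 fell 41.4-fold, KRT5 18.1-fold, KRT17 11.9-fold and KRT6A 11.1-fold. The tight junction protein gene CLDN4 fell 26.5-fold, the membrane proteolipid gene MAL2 18.6-fold and ESRP1 12.95-fold. In YB-1 cells ESRP1 stood at 2.80, under the lower quartile of genes, and RAB25 (3.24) and CLDN4 (3.47) close to it, so these folds are not exact. FN1 rose 7.33-fold (log2 difference 2.87 ± 0.19, limma adjusted p = 0.00045), SRGN 9.49-fold, DCN 7.65-fold and SPARC 6.32-fold.

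Among the groups, 15 of the 39 epithelial genes fell in polysomal RNA, 0 rose and 24 did not pass the test. Adjusted over the list alone, 21 fell. The list's median was -0.54, with a camera adjusted p = 1.02e-21 and an adjusted p = 0.368 with an estimated correlation. Of the 25 basal genes, 12 fell and 0 rose (16 fell adjusted over the list alone), with a median of -1.12, a camera adjusted p = 6.64e-22 and an adjusted p = 0.368 with an estimated correlation. Of the 43 mesenchymal and matrix genes, 7 rose and 0 fell (8 rose adjusted over the list alone), with a median of 0.09, a camera adjusted p = 3.82e-07 and an adjusted p = 0.368 with an estimated correlation. Besides FN1, DCN and SPARC, these included the actin-binding protein gene TAGLN (4.19-fold) and the intermediate filament gene VIM (2.39-fold).

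In other lists few or no single genes passed in polysomal RNA. Of 31 ATF4 target genes, 4 fell in polysomal RNA (7 adjusted over the list alone) and the median was -0.35, with a camera adjusted p = 4.91e-05 and an adjusted p = 0.715 with an estimated correlation. The amino acid transporter gene SLC7A5 fell 3.87-fold, its partner chain SLC3A2 2.29-fold, the stress protein gene NUPR1 3.04-fold and the serine synthesis enzyme gene PHGDH 2.18-fold. Of 22 immediate early genes, 2 fell, EGR1 by 2.16-fold and the kinase gene SGK1 by 2.51-fold (5 fell and 1 rose adjusted over the list alone). Their median was -0.37, with a camera adjusted p = 0.00156 and an adjusted p = 0.715 with an estimated correlation. Of 32 hypoxia genes, the glucose transporter gene SLC2A3 rose 3.64-fold and 0 fell (5 rose and 1 fell adjusted over the list alone). The hypoxia median was 0.05, with a camera adjusted p = 0.000631 and an adjusted p = 0.715 with an estimated correlation. Of 41 DNA replication genes, only the polymerase subunit gene POLE2 fell, by 3.25-fold (2 fell adjusted over the list alone). The list's median was -0.38, with a camera adjusted p = 2.22e-05 and an adjusted p = 0.715 with an estimated correlation. Chaperone genes had a median of -0.49 with 0 of 19 past the test (1 lower adjusted over the list alone), a camera adjusted p = 0.000112 and an adjusted p = 0.715 with an estimated correlation. Among 18 immune cell genes, the macrophage-associated lysosomal gene CD68 rose 2.28-fold and 17 did not pass, and of 11 endothelial genes 0 passed.

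In all, 226 of 15719 genes passed limma's test in polysomal RNA, 45 higher and 181 lower (19.9% higher), and 1790 had an unadjusted p under 0.05. After centring each array on its median, 560 passed (126 higher and 434 lower), and after quantile normalization 469 passed (152 higher and 317 lower, 32.4% higher). With the 4 polysomal arrays alone, 697 passed. Leaving out polysomal MSCV array A gave 50 genes, MSCV array B 58, YB-1 array A 66 and YB-1 array B 79, and leaving out either post-polysomal MSCV array gave 440. RAB25, KRT15, KRT5, KRT17, KRT6A, CLDN4, MAL2, ESRP1, FN1, SRGN, DCN and SPARC passed without each of the 8 arrays. TAGLN was lost without polysomal MSCV array A (adjusted p = 0.0679) or B (0.0692), and SLC7A5 without MSCV array B (0.0659) or YB-1 array A (0.0566). NUPR1 was lost without polysomal MSCV array A (0.0607) or B (0.0587) or YB-1 array A (0.0551), and SLC2A3 without MSCV array A (0.0515) or YB-1 array A (0.0735) or B (0.0883). VIM and CD68 were lost without any of the 4 polysomal arrays (adjusted p up to 0.265 for VIM and 0.221 for CD68). EGR1, SGK1, SLC3A2, PHGDH and POLE2 were each lost on leaving out any 1 array except a post-polysomal MSCV array (adjusted p up to 0.265, 0.422, 0.392, 0.411 and 0.362). EGR1 and PHGDH were not called after quantile normalization (adjusted p = 0.0663 and 0.0551), nor EGR1, SGK1, SLC3A2 and PHGDH with the trend and robust option (0.0576, 0.054, 0.0637 and 0.0746).

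In post-polysomal RNA of YB-1 cells, adhesion genes of epithelium fell and several matrix genes rose. CDH1, which encodes E-cadherin (row 201131_s_at, hg16 chromosome 16, 68547412 to 68644065), fell 21.5-fold (log2 difference -4.43 ± 0.30, n = 2 arrays per line, limma adjusted p = 0.000242). The tight junction gene CLDN1 fell 66.2-fold (-6.05 ± 0.31), RAB25 54.4-fold (-5.77 ± 0.26) and ESRP1 44.5-fold (-5.48 ± 0.21). The desmosomal cadherin genes DSC3, DSG3 and DSC2 fell 37.5-fold, 30.4-fold and 18.3-fold. In YB-1 cells CDH1 (3.11), RAB25 (2.97), ESRP1 (3.19) and DSC3 (2.56) lay under the lower quartile of genes, so their folds are not exact. CDH2, which encodes the mesenchymal N-cadherin (row 203440_at, hg16 chromosome 18, 23783376 to 23837944), rose 4.44-fold (2.15 ± 0.27, adjusted p = 0.00500). In polysomal RNA CDH2 differed by 0.86 ± 0.27 and did not pass (adjusted p = 0.265), but it passed after centring (0.0306) and quantile normalization (0.0488), with an adjusted p of 0.0306 to 0.812 over all alternatives. SPARC rose 11.7-fold, DCN 11.1-fold, FN1 10.4-fold and FBN1, the microfibril protein gene, 6.19-fold from a level of 3.23 in MSCV cells, close to that quartile.

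By group, 26 of the 39 epithelial genes fell in post-polysomal RNA and 0 rose (30 fell adjusted over the list alone). Their median was -1.78, with a camera adjusted p = 4.93e-42 and an adjusted p = 0.161 with an estimated correlation. Of the 25 basal genes, 18 fell and 0 rose (23 fell adjusted over the list alone), with a median of -1.88, a camera adjusted p = 4.79e-37 and an adjusted p = 0.161 with an estimated correlation. Of the 43 mesenchymal and matrix genes, 14 rose and 2 fell (15 and 4 adjusted over the list alone), with a median of 0.30, a camera adjusted p = 6.18e-10 and an adjusted p = 0.161 with an estimated correlation. The genes that fell were the matrix glycoprotein gene TNC (-2.55, adjusted p = 0.00206) and the membrane metalloproteinase gene MMP14 (-1.13, adjusted p = 0.0288), both named after their values were seen. Luminal breast genes had a median of -0.11, and 3 of 17 fell, the receptor gene ERBB3 4.14-fold, the luminal transcription factor gene GATA3 2.19-fold and AGR2, a disulfide isomerase gene, 4.98-fold (4 fell adjusted over the list alone). ERBB3 (3.01) and AGR2 (2.36) lay under the lower quartile in YB-1 cells. The list's camera adjusted p was 0.0307, and the adjusted p = 0.853 with an estimated correlation.

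Other lists in post-polysomal RNA covered signalling, hypoxia and stress genes. Of the 22 immediate early genes, 8 fell and 0 rose (13 fell and 1 rose adjusted over the list alone), with a median of -0.79, a camera adjusted p = 1.08e-07 and an adjusted p = 0.853 with an estimated correlation. Among the transcription factor genes of that list, EGR1 fell 2.93-fold, EGR2 2.95-fold, FOSB 2.64-fold and NR4A1 2.18-fold. Of 21 MAPK output genes, 4 fell, among them MYC by 2.04-fold and the ephrin receptor gene EPHA4 by 2.54-fold (6 fell and 2 rose adjusted over the list alone). Their median was -0.24, with a camera adjusted p = 0.00569 and an adjusted p = 0.980 with an estimated correlation. Of 32 hypoxia genes, 7 rose and 1 fell (9 and 5 adjusted over the list alone), with a median of 0.23, a camera adjusted p = 0.00569 and an adjusted p = 0.980 with an estimated correlation. SLC2A3 rose 8.55-fold, the glycolytic enzyme gene ENO2 4.31-fold and the collagen-modifying enzyme gene PLOD2 2.96-fold, and the glucose transporter gene SLC2A1 fell 1.98-fold. Of the 31 ATF4 targets, 3 fell, led by SLC7A5 at 10.6-fold (4 fell adjusted over the list alone), with a median of -0.25, a camera adjusted p = 0.00507 and an adjusted p = 0.980 with an estimated correlation. Proteasome subunits had a median of 0.30 with 0 of 30 past the test and 0 adjusted over the list alone, a camera adjusted p = 0.0120 and an adjusted p = 0.980 with an estimated correlation. CD68 rose 2.88-fold as 1 of 18 immune genes, and 0 of 11 endothelial genes passed.

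In all, 570 genes passed in post-polysomal RNA, 205 higher and 365 lower (36% higher), and 2174 had an unadjusted p under 0.05. Centring gave 1163 genes, quantile normalization 1242, and the 4 post-polysomal arrays alone 83. Leaving out post-polysomal MSCV array A, the lower of that pair, gave 1139 genes (188 higher and 951 lower), and leaving out MSCV array B gave 585 (333 higher and 252 lower). Leaving out post-polysomal YB-1 array A gave 255 and array B 232, and leaving out either polysomal MSCV array gave 294 and either polysomal YB-1 array 338. CDH1, CLDN1, RAB25, ESRP1, DSC3, DSG3, DSC2, FBN1, SPARC, DCN, FN1, SLC2A3, ENO2 and SLC7A5 passed without each of the 8 arrays and with the 4 arrays alone. CDH2, ERBB3, EGR1, PLOD2 and CD68 passed without each array and were lost with the 4 arrays alone (adjusted p = 0.0728, 0.0512, 0.0577, 0.0757 and 0.0891). MYC, NR4A1, FOSB, EPHA4 and SLC2A1 were lost without post-polysomal YB-1 array A or B (adjusted p up to 0.0727, 0.0816, 0.125, 0.0761 and 0.108). EGR2 was lost without either post-polysomal YB-1 array or either polysomal MSCV array (up to 0.119). AGR2 was lost without either post-polysomal YB-1 array or any polysomal array (up to 0.191), and GATA3 without these or post-polysomal MSCV array B (up to 0.189). MYC, NR4A1, FOSB, EPHA4, SLC2A1, EGR2, AGR2 and GATA3 were also lost with the 4 arrays alone (adjusted p up to 0.279), and GATA3 with the mean over exon-level probesets (0.0629). The luminal list was no longer called with the mean over exon-level probesets (adjusted p = 0.0910, and 0.00598 to 0.853 over all alternatives).

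The transcription factors that drive epithelial-mesenchymal transition were the study's own question, since YB-1 has been examined as a regulator of their translation. SNAI1, which represses CDH1 (row 219480_at, hg16 chromosome 20, 49284958 to 49290845), stood at 3.69 in polysomal RNA of MSCV cells and 4.35 in YB-1 cells, a difference of 0.66 ± 0.19 that did not pass (n = 2 arrays per line, limma adjusted p = 0.210). In post-polysomal RNA SNAI1 rose 2.07-fold (1.05 ± 0.19, adjusted p = 0.0248), while its total RNA value was lower in YB-1 cells (-0.79, 1 array per line). TWIST1 (row 213943_at, hg16 chromosome 7, 18900609 to 18901327) differed by 0.88 ± 0.20 in polysomal RNA (adjusted p = 0.107), rose 2.07-fold in post-polysomal RNA (1.05 ± 0.20, adjusted p = 0.0306) and differed by 0.60 in total RNA. ZEB1, another CDH1 repressor (row 210875_s_at, hg16 chromosome 10, 31753971 to 31820387), rose 3.31-fold in post-polysomal RNA (1.73 ± 0.19, adjusted p = 0.00319) and differed by 0.27 in polysomal RNA (adjusted p = 0.707). ZEB1 stood at 2.65 in post-polysomal RNA of MSCV cells and at 2.42 and 2.69 in the polysomal RNA of MSCV and YB-1 cells, all under the lower quartile of genes, so its values are not shown to lie above background and its fold is not exact. SNAI2 differed by -0.34 in polysomal RNA (adjusted p = 0.617) and by -0.66 in post-polysomal RNA (adjusted p = 0.157), and its total RNA value was lower in YB-1 cells (-0.89). LEF1, TCF4 and HIF1A passed in neither fraction, the total RNA values of TCF4 and LEF1 differed by -0.81 and -0.17, and HIF1A differed by 0.97 in polysomal RNA (adjusted p = 0.277). CDH1 itself differed by -1.30 ± 0.30 in polysomal RNA (adjusted p = 0.115), where its MSCV level was 4.52 against 7.53 in post-polysomal RNA. CDH1 passed there after centring (adjusted p = 0.00415) and after quantile normalization (0.00693), with an adjusted p of 0.00415 to 0.566 over all alternatives.

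As a list, 17 EMT transcription factors gave 0 genes past in polysomal RNA (1 higher adjusted over the list alone), with a median of 0.03 and a camera adjusted p = 0.0667. In post-polysomal RNA 3 rose and 1 fell (4 and 2 adjusted over the list alone). The gene that fell was SOX9 (2.21-fold), and the list's median of -0.18 was opposite in sign to its mean of 0.06 and to the higher direction of the test (camera adjusted p = 0.961). In total RNA the list's median was -0.22, at percentile 3.07 of random lists, with 0 members at least 2-fold higher and 2 at least 2-fold lower. The interaction did not pass for SNAI1, TWIST1, ZEB1 (limma interaction adjusted p = 0.780, 0.942 and 0.274) or CDH1 (interaction 3.12, adjusted p = 0.127). That leaves open whether their differences between the lines differed between the fractions. The interaction test recovered 0 of 200 simulated changes of 1 log2 unit and 185 of 200 of 2 log2 units. These shares do not apply to CDH1, whose interaction had an SE of 0.43, against 0.23 to 0.32 for the genes whose interaction passed. In YB-1 cells CDH1 stood at 3.21 in polysomal and 3.11 in post-polysomal RNA, near or under the lower quartile of genes. In MSCV cells it stood at 4.52 and 7.53, so CDH1 had less room to fall in polysomal RNA. Its interaction cannot be told apart from that limit. The CDH1 interaction passed without the dimmest genes (0.0282), after centring (0.000176), after quantile normalization (0.0105), with trend and robust (0.0447) and without post-polysomal MSCV array A (0.00640) or B (0.0429), with an adjusted p of 0.000176 to 0.720 over all alternatives. The post-polysomal call of SNAI1 was lost without either YB-1 array of either fraction (adjusted p up to 0.154) and with the 4 arrays alone (0.129). The call of TWIST1 was lost without every array but post-polysomal MSCV array B (up to 0.192), that of ZEB1 only with the 4 arrays alone (0.0769), and that of SOX9 without post-polysomal YB-1 array A (0.0539) or B (0.101). With the 4 arrays alone TWIST1 (0.188) and SOX9 (0.108) were lost as well.

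Most genes called in polysomal RNA moved the same way in post-polysomal RNA. Of 45 genes higher in polysomal RNA, 40 were also higher in post-polysomal RNA, against 0.59 for independent lists. Of 181 lower genes, 127 were also lower, against 4.20, and 0 genes were called in opposite directions. These comparisons share no arrays but share an estimate of the spread. All 40 higher and all 127 lower genes moved the same way in total RNA, with median total RNA differences of 1.67 and -2.62. Across all genes, the differences between the lines in total RNA correlated with those in polysomal RNA at Pearson r = 0.513 and Spearman rho = 0.207, and with those in post-polysomal RNA at r = 0.739 and rho = 0.507. The fractions correlated with each other at r = 0.552 and rho = 0.244. These 3 correlations are across genes, which are not independent replicates.

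**Figure D2:**
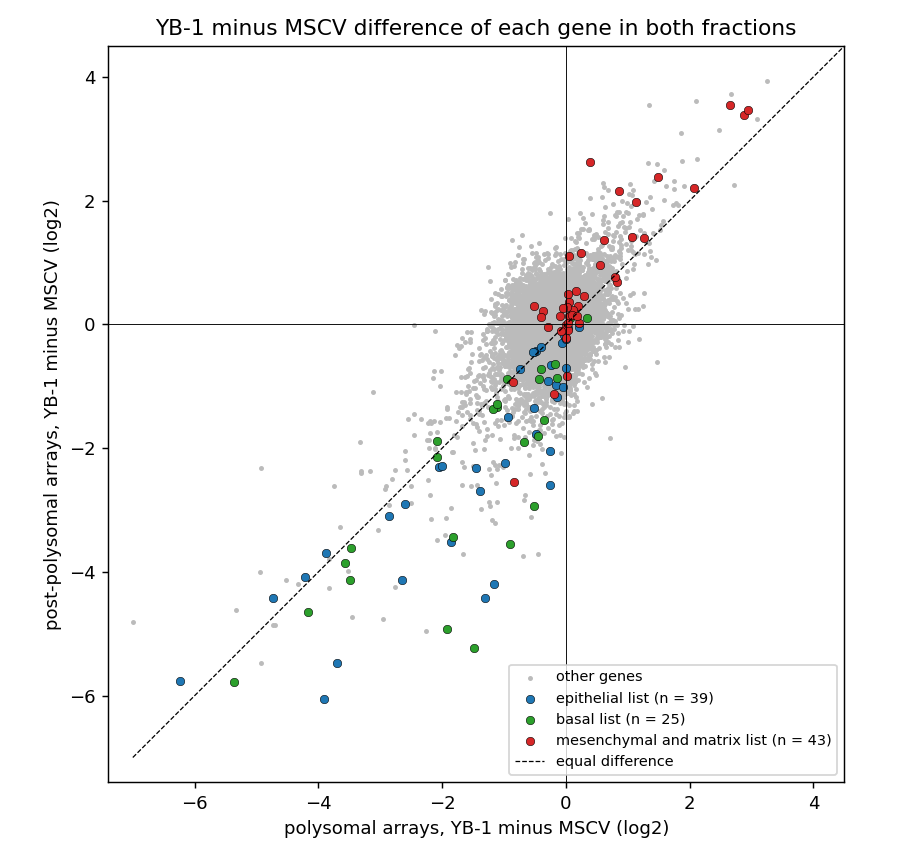
YB-1 minus MSCV log2 difference in polysomal RNA (x axis) against that in post-polysomal RNA (y axis), with 1 point per gene and the dashed line at equal differences. Epithelial genes (blue, n = 39) and basal genes (green, n = 25) reached down to -6.24 in polysomal RNA, mesenchymal and matrix genes (red, n = 43) reached up to 2.94, and grey points are other genes.

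The interaction asked for which genes the difference between the lines was not the same in the fractions, and 5 genes passed. DSC3 (row 206032_at, hg16 chromosome 18, 26821960 to 26874675) fell from 7.79 to 2.56 in post-polysomal RNA and from 3.95 to 2.46 in polysomal RNA, an interaction of 3.74 ± 0.32 (n = 2 arrays per group, limma adjusted p = 0.0272). The other genes with a smaller difference in polysomal RNA were FAT2, an atypical cadherin gene (3.04 ± 0.23, adjusted p = 0.0212), DSC2 (3.04 ± 0.30, adjusted p = 0.0380) and PROM2, an epithelial membrane protein gene (2.55 ± 0.25, adjusted p = 0.0380). FBN1 differed less in polysomal RNA (-2.24 ± 0.24, adjusted p = 0.0495), from 2.90 to 3.29 against 3.23 to 5.86 in post-polysomal RNA. The lower levels of DSC3 and FBN1 and those of DSC2 (3.06) and FAT2 (3.20) in polysomal YB-1 RNA lay near or under the lower quartile of genes. In all 1193 genes had an unadjusted p under 0.05. Centring gave 80 genes (53 positive, 27 negative, 66.2% positive against 80%), quantile normalization 52 (46 positive, 6 negative), the dim-gene filter 11 and the trend and robust option 12. Leaving out any polysomal array or either post-polysomal YB-1 array gave 0 genes, leaving out post-polysomal MSCV array A gave 72 and array B 13. With the mean over exon-level probesets, DSC2 (adjusted p = 0.0959) and FBN1 (0.0590) were not called, and over all alternatives their adjusted p ran up to 0.465 and 0.543.

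Between the fractions of each line, transcripts of mitochondrial respiration, nucleosomes and ribosomes stood high in polysomal RNA, and transcripts of chaperones, mRNA-binding proteins and mitosis stood high in post-polysomal RNA. In MSCV cells, ATP5F1E, an ATP synthase subunit gene, was 10.4-fold higher in polysomal RNA (3.38 ± 0.28, n = 2 arrays per fraction, limma adjusted p = 0.000198), and NDUFB6, a complex I subunit gene, 12.98-fold higher. The histone gene H4C4 was 10.6-fold higher, with the reservation that histone genes have near-identical copies. The mitochondrial iron carrier gene SLC25A37 was 24.5-fold lower, the noncoding RNA TUG1 22.7-fold, the hemidesmosomal integrin gene ITGA6 17.99-fold and the deadenylase scaffold gene CNOT1 17-fold lower. In YB-1 cells ATP5F1E was 5.39-fold and the histone gene H3C1 6.21-fold higher in polysomal RNA. SLC25A37 was 23.3-fold, the nuclear noncoding RNA MALAT1 21.5-fold and ITGA6 17.2-fold lower. The folds of SLC25A37 (2.63 and 2.27 in polysomal RNA of MSCV and YB-1 cells) and TUG1 (2.95 in MSCV cells) are not exact, as these levels lay under the lower quartile.

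Of 77 nuclear-encoded oxidative phosphorylation genes, 63 were higher and 2 lower in polysomal RNA of MSCV cells (65 and 2 adjusted over the list alone), and 50 were higher and 2 lower in YB-1 cells (60 and 3 adjusted over the list alone). Relative to the median of all genes, the list stood at 1.37 in MSCV cells (camera adjusted p = 4.44e-21, adjusted p = 0.439 with an estimated correlation) and at 1.01 in YB-1 cells (3.33e-18, adjusted p = 0.551 with an estimated correlation). Of 33 replication-dependent histone genes, 32 were higher in MSCV cells and 29 in YB-1 cells, with the same counts adjusted over the list alone. Their relative medians were 1.68 (camera adjusted p = 2.81e-19, adjusted p = 0.439 with an estimated correlation) and 1.24 (1.78e-18, adjusted p = 0.542 with an estimated correlation). Of 55 ribosomal protein genes, 32 and 28 were higher and 0 were lower (36 and 35 adjusted over the list alone), with relative medians of 0.66 and 0.64. Not taken relative to all genes, the medians were 0.668 and 0.604, against 0.805 and 0.413 for lists matched on exon probesets and level. RNA size was therefore not separated from the place of the ribosomal protein genes. Their camera adjusted p was 4.90e-12 in MSCV cells (adjusted p = 0.439 with an estimated correlation; 0.0720 after quantile normalization, and 1.12e-12 to 0.439 over all alternatives) and 7.97e-17 in YB-1 cells (adjusted p = 0.551 with an estimated correlation), and ribosomal protein genes have many near-identical copies.

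Chaperones and mRNA-binding proteins stood on the other side. Among genes brighter than the median, those with the most exon probesets (20 to 122) had a median difference of -1.21 in MSCV and -1.18 in YB-1 cells. The lists low in polysomal RNA were not matched on exon probesets, so RNA size was not separated from their place. Of 19 chaperone genes, 11 were lower and 2 higher in polysomal RNA of MSCV cells, and 12 lower and 0 higher in YB-1 cells (12 and 2, then 15 and 0, adjusted over the list alone), with relative medians of -1.21 and -1.39. HSP90AA1 was 5.93-fold and 6.76-fold lower. The camera adjusted p was 0.00163 in MSCV cells and 2.05e-05 in YB-1 cells (adjusted p = 0.596 and 0.551 with an estimated correlation). Of 19 cold shock domain and mRNP protein genes, 13 were lower in each line and 1 higher (13 and 2 adjusted over the list alone), with relative medians of -1.42 and -1.66. The hnRNP gene HNRNPU was 8.38-fold and 12.99-fold lower. The camera adjusted p was 0.00188 and 0.000476 (adjusted p = 0.439 and 0.551 with an estimated correlation). Of 39 mitosis genes, 21 were lower and 6 higher in MSCV cells, and 25 lower and 3 higher in YB-1 cells (23 and 8, then 29 and 3, adjusted over the list alone). TOP2A, the topoisomerase of dividing cells, was 11.6-fold and 10.1-fold lower. The relative medians were -0.94 and -1.38, with a camera adjusted p = 0.00632 and 3.39e-05 (adjusted p = 0.708 and 0.551 with an estimated correlation). HIF1A was 8.07-fold lower in polysomal RNA of MSCV cells (-3.01 ± 0.31, limma adjusted p = 0.000379).

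**Figure D3:**
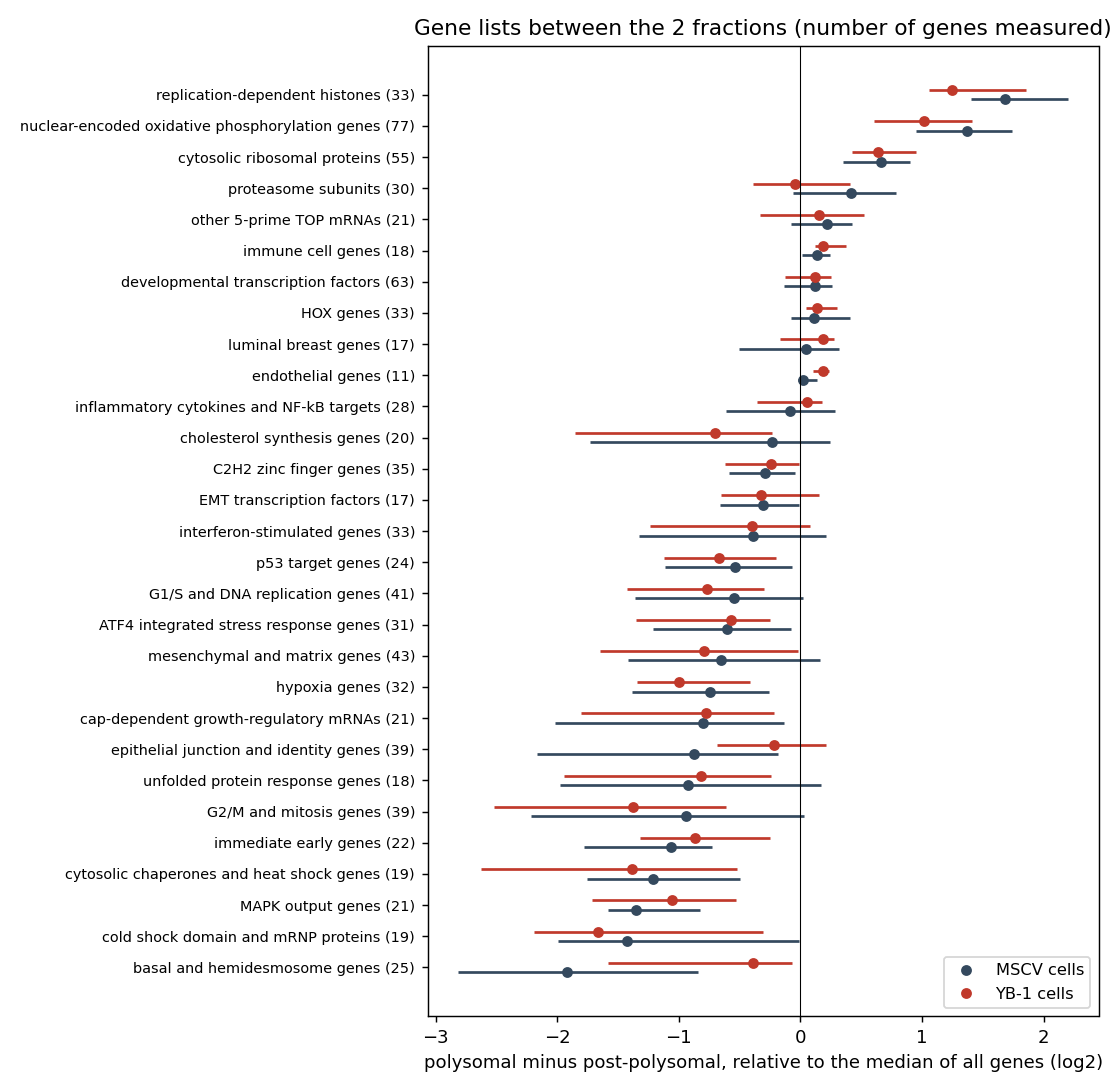
Polysomal minus post-polysomal log2 difference (x axis), relative to the median of all genes, for 29 gene lists (y axis) in MSCV cells (blue) and YB-1 cells (red). Points are list medians and lines run between quartiles, with histones at 1.68 and 1.24 and cold shock domain and mRNP genes at -1.42 and -1.66.

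In MSCV cells 5414 genes differed between the fractions, 1547 higher and 3867 lower in polysomal RNA (28.6% higher), with 6631 at an unadjusted p under 0.05. In YB-1 cells 4602 differed, 744 higher and 3858 lower (16.2% higher), with 6069 at an unadjusted p under 0.05. The split rested on the scaling. Centring each array on its median moved the median of all genes from 0.01 to 0.55 in MSCV cells and from -0.03 to 0.50 in YB-1 cells, and gave 11119 genes (8334 higher and 2785 lower, 75% higher) and 10446 genes (7665 higher and 2781 lower, 73.4% higher). Quantile normalization gave 7137 genes in MSCV cells (3885 higher and 3252 lower, 54.4% higher) and 6901 in YB-1 cells (3872 higher and 3029 lower, 56.1% higher). The count fell to 3313 in MSCV cells without polysomal MSCV array A, and in YB-1 cells to 2790 without polysomal YB-1 array A and to 2823 without post-polysomal YB-1 array B. The calls of the lines shared 632 higher and 3135 lower genes, against 73.2 and 949.1 for independent lists.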

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

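In this part, the tests of room to fall, of the size trend of the interaction, of a shift between the fractions alone and of immune cells were chosen only after the results were seen.

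The results below stood out because the difference between the lines was itself different between the fractions, by limma's interaction. DSC3 had an interaction of 3.74, FAT2 of 3.04, DSC2 of 3.04 and PROM2 of 2.55, all epithelial adhesion or membrane genes with the smaller difference in polysomal RNA, and FBN1 had -2.24. Of these 5 genes, 0 stayed past the test in all the alternatives that kept every array. Low levels limit DSC3, FAT2, DSC2 and FBN1, as given above. Epithelial genes had a median interaction of 0.41 (camera adjusted p = 3.69e-15) and basal genes of 0.45 (4.38e-13). Oxidative phosphorylation genes had -0.33 (5.24e-06), histones -0.46 (0.000463), proteasome subunits -0.41 (0.00128) and mitosis genes -0.49 (0.00329). Mesenchymal and matrix genes had -0.23 (0.0115), immediate early genes 0.12 (0.0125) and chaperones -0.30 (0.0248). Each of these 9 lists had an adjusted p = 0.912 with an estimated correlation. After quantile normalization the calls of oxidative phosphorylation (0.0529), histones (0.177), proteasome (0.321) and chaperones (0.546) ended, and without the dimmest genes those of the mesenchymal list and the chaperones (0.0607 for both).

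The size of the transcript was weighed first, because oxidative phosphorylation, histone and ribosomal protein genes stood high in polysomal RNA and have few exon probesets (medians of 7, 3 and 6), which stand here for RNA size. Across 7859 genes brighter than the median, the polysomal minus post-polysomal difference fell with the number of exon probesets per gene, at Spearman rho = -0.559 in MSCV cells and -0.528 in YB-1 cells, from a median of 0.44 for the genes with the fewest probesets (1 to 9) to -1.21 for those with the most (20 to 122) in MSCV cells. The number of probesets did not account for the oxidative phosphorylation and histone lists, whose medians lay at percentile 100 of lists matched on probesets and level in both lines. Transcript length itself was not measured or matched, so size is not excluded for these lists. For ribosomal proteins (percentiles 20.18 in MSCV and 92.63 in YB-1 cells) size and translation cannot be told apart. The polysomal minus total RNA difference had rho = -0.521 in MSCV and -0.462 in YB-1 cells and the post-polysomal minus total RNA difference 0.417 and 0.342, so a shortage of long RNAs in the polysomal arrays and an excess in the post-polysomal arrays cannot be told apart. Breakage of long RNAs in the polysomal material and a true difference in ribosome loading both stay open as causes of the trend. The lists that stood low in polysomal RNA were not matched on probesets, so size stays open for them as well.

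The smaller difference of epithelial and basal genes in polysomal RNA was weighed next. The median interaction of the 64 members (0.43) lay at percentile 98.78 of 10000 lists of other genes matched on probesets (median 16 against 18), total RNA level and fall in total RNA, whose median was 0.21, and at percentile 100 of lists matched without the fall (-0.09). With the members resampled, a bound added after those percentiles were seen, the difference from the genes with the same fall ran from -0.056 to 0.525, and among the 42 members at least 2-fold lower in total RNA the interaction was larger with more probesets (rho = 0.53, permutation p = 0.00045 over 42 genes, which are not independent), so the RNA size trend of the fractions and a property of these genes cannot be told apart. Low polysomal signal leaves less room to fall, and of these 42 the 20 members dim in polysomal MSCV array A had a median interaction of 1.36 in the other 7 arrays against 0.33 (quartiles 0.11 to 0.57) for the 22 bright members. Since the bright members still lay above 0, limited signal and a real retention in polysomes cannot be told apart for them, and a biological difference in how long these mRNAs stay on ribosomes remains untested.

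The loss of epithelial and the gain of matrix transcripts in YB-1 cells was weighed last. A shift between polysomal and post-polysomal RNA alone would move a gene in opposite directions in the fractions, and it was excluded for the genes called in both, since 27 of 64 epithelial and basal genes fell in both fractions, 7 of 43 mesenchymal and matrix genes rose in both, and 0 of either group were called in opposite directions. Immune cells in the YB-1 culture would raise many immune genes, but 1 of 18 (CD68) was higher in both fractions, which argues against a large share of such cells. A small share is not excluded, since the smallest difference called in polysomal RNA was 0.803. In total RNA CD14 stood at 8.94 in MSCV and 8.90 in YB-1 cells, TYROBP at 5.35 and 5.17 and LYZ at 2.07 and 1.84, and the labels name no sort. Of the 18 genes, 3 lay above the median gene in total RNA of MSCV cells. Transcription, mRNA stability, a move to parts of the gradient not measured and a difference between the lines other than the vector all stay open, because the labels name 1 line for each vector and total RNA, where 42 of the 64 genes were at least 2-fold lower, has 1 array per line.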

How the results depend on the processing

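The tests in this part were all planned, except that which arrays decided a call was read from the results. Signal over background limits the depth, and with 1 array of a group left out the lone array was assumed to vary like the other groups. Genes past the test in polysomal RNA numbered 560 after centring, 469 after quantile normalization and 697 with 4 arrays, and 50 to 440 with 1 array left out. In post-polysomal RNA they numbered 1163, 1242 and 83, and 232 to 1139. The interaction gave 80 genes after centring, 52 after quantile normalization, 11 without the dimmest genes and 12 with trend and robust, and 0 to 72 with 1 array left out. Between the fractions, centring gave 11119 genes in MSCV and 10446 in YB-1 cells, and leaving out 1 array gave 3313 to 5931 and 2790 to 5608. Of 145 list tests 70 were called, 0 with an estimated correlation and 60 to 69 under the other alternatives. The correlation across genes of the line differences in total and polysomal RNA became 0.537 without the dimmest genes and 0.479 with the mean over exon-level probesets. Where a named gene or list passed the test as reported or under the alternative, directions turned in 3 cases: the proteasome list between the fractions of MSCV cells after quantile normalization (adjusted p = 0.343, lower), TWIST1 between the fractions of MSCV cells after centring (0.54 against -0.01), and zinc finger protein 76 between the fractions of YB-1 cells after quantile normalization (0.06 against -0.62). Another 32 results of named genes that passed in neither setting changed sign, 8 after centring, 5 after quantile normalization, 3 with the mean over exon-level probesets and 16 with 1 array left out. Among all called genes, the sign changed between the fractions of MSCV cells for 43 after centring, 71 after quantile normalization, 7 with the mean over a gene's rows and 1 with the mean over exon-level probesets. In YB-1 cells it changed for 19, 93 and 1 in the first 3 of these settings. The cause of these changes was not tested. For named genes with 1 array left out, 4827 results kept their side of the threshold, 319 lost the call and 86 gained one. The 4827 include the 16 that changed sign and passed in neither setting. The alternatives planned for YBX1 were not run.

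The replicate letter as a block over all 8 arrays gave 266 genes in polysomal RNA, 670 in post-polysomal RNA, 5 for the interaction, 5825 and 5034 between the fractions of MSCV and YB-1 cells, and 69 lists. Blocks of letter within each line gave 0 genes for the interaction (adjusted p = 0.192 for the 5 called without it), and 5012 and 4211 between the fractions. Deviations of same-lettered arrays correlated at 0.214 (polysomal MSCV and YB-1), -0.04 (polysomal and post-polysomal MSCV), -0.124 (polysomal MSCV and post-polysomal YB-1), 0.169 (polysomal YB-1 and post-polysomal MSCV), -0.055 (polysomal and post-polysomal YB-1) and 0.488 (post-polysomal MSCV and YB-1), and the labels tie no arrays together by letter. The correlations of the post-polysomal arrays and of the polysomal arrays of the lines leave a shared factor open, but not every pair exceeded 0.1, so the letter was not taken to pair the arrays.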

Other observations

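No test in this part was chosen after its result was seen. Outside the epithelial, basal and matrix lists, large differences in polysomal RNA of YB-1 cells included the following genes. FXYD3, a regulator of ion transport, fell 30.4-fold (log2 difference -4.93 ± 0.22, n = 2 arrays per line, limma adjusted p = 8.28e-05), the tetraspanin gene TSPAN1 26.7-fold, the vitamin B12 carrier gene TCN1 26.05-fold and ART3 40.2-fold. The chemokine gene CXCL11 fell 30.9-fold and AGR2 30.4-fold, and the histone gene H3C3, which has near-identical copies, 127-fold, the largest of these. In polysomal YB-1 RNA ART3 (2.71), CXCL11 (2.86) and AGR2 (2.55) lay under the lower quartile of genes and H3C3 (3.16) close to it, as did PTX3 (3.19) and TNFAIP6 (3.17) in polysomal MSCV RNA, so these folds are not exact. Among the genes that rose were the formyl peptide receptor gene FPR1 (6.54-fold), the pentraxin gene PTX3 (8.48-fold), TNFAIP6, which encodes a hyaluronan-binding protein (6.35-fold), the ganglioside synthesis gene ST3GAL5 (5.56-fold), RTN1 (4.30-fold) and the anticoagulant protein gene PROS1 (4.36-fold). In post-polysomal RNA SRGN rose 15.2-fold, TNFAIP6 13.2-fold (from 2.59, under the lower quartile), RTN1 12.3-fold, the G protein subunit gene GNG11 11.6-fold and ST3GAL5 8.83-fold, and TCN1 and TSPAN1 fell 29.05-fold and 28.9-fold. The polysomal calls were lost without MSCV array A for CXCL11 (adjusted p = 0.0607), TNFAIP6 (0.0855) and AGR2 (0.0615), without MSCV array B for TNFAIP6 (0.122), AGR2 (0.0515) and PTX3 (0.0811), without YB-1 array A for PTX3 (0.0725), and without any polysomal array for PROS1 (up to 0.132). The post-polysomal call of GNG11 was lost with the 4 arrays alone (0.095).

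Some lists that were not called in post-polysomal RNA held single genes past the test. Of 33 interferon-stimulated genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), IFIT1 3.78-fold, IFI44L 3.41-fold and BST2 2.14-fold, with a median of 0.00 and a camera adjusted p = 0.609. Of 28 inflammatory genes, the chemokine gene CCL20 rose 3.14-fold and the cytokine genes IL1A and LIF fell 5.09-fold and 2.48-fold (4 rose and 5 fell adjusted over the list alone). Their median of 0.03 was opposite in sign to the mean of -0.09 and the test (camera adjusted p = 0.583). Of 21 mRNAs of growth regulators taken to depend on cap-binding translation factors, 3 rose and 2 fell (3 and 4 adjusted over the list alone), among them the survival gene BCL2L1 (2.71-fold higher) and the growth factor gene FGF2 (1.72-fold higher), with a camera adjusted p = 0.961. Of 63 developmental transcription factor genes, 2 rose and 3 fell (3 and 4 adjusted over the list alone), with TBX3 2.31-fold higher and the Notch target HES1 4.01-fold lower, and a camera adjusted p = 0.918. HES1 fell 4.31-fold in polysomal RNA too. HES1 was lost in polysomal RNA without any polysomal array (adjusted p up to 0.147) and in post-polysomal RNA with the 4 arrays alone (0.0732), and all the other genes of this paragraph were lost there too (0.101 to 0.227). Leaving out post-polysomal YB-1 array A ended BCL2L1 (0.0937), TBX3 (0.067) and IFI44L (0.0651), and array B also ended IFI44L (0.127). LIF was lost without either YB-1 array of either fraction (up to 0.117), and IFIT1 without these or either polysomal MSCV array (up to 0.132). BST2 was lost without any polysomal array, post-polysomal MSCV array B or YB-1 array A (up to 0.170). CCL20 and FGF2 were lost without any array but post-polysomal MSCV array B (up to 0.238 and 0.207), FGF2 also with trend and robust (0.0753) or the mean over exon-level probesets (0.0911), and IL1A without any but post-polysomal MSCV array A (up to 0.219).

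Several lists were called lower in polysomal RNA of YB-1 cells with few or no single genes past the test. Histones had a median of -0.37 (0 of 33 past, 0 adjusted over the list alone, camera adjusted p = 4.23e-05) and oxidative phosphorylation genes -0.26 (0 of 77 past, 0 adjusted over the list alone, 0.000115), with an adjusted p = 0.688 and 0.777 with an estimated correlation and 0.0682 for both after quantile normalization. The histone list does not hold H3C3, whose row has 1 exon probeset. The p53 target list (median -0.32, 0 of 24 past and 0 adjusted over the list alone, camera adjusted p = 0.0183) had an adjusted p = 0.771 with an estimated correlation. It ran from 0.00959 to 0.771 over the alternatives, with 0.0694 without the dimmest genes and 0.128 after quantile normalization. The MAPK list (median -0.20, camera adjusted p = 0.0316) had 1 of 21 past, EGR1 (3 adjusted over the list alone), and an adjusted p = 0.771 with an estimated correlation and 0.0322 to 0.771 over the alternatives. Its call ended without the dimmest genes (0.132), after centring (0.0824) or quantile normalization (0.265), and with the mean over exon-level probesets (0.0710). The cold shock domain and mRNP list (median -0.26, 0 of 19 past and 0 adjusted over the list alone, camera adjusted p = 0.0494) had an adjusted p = 0.715 with an estimated correlation, and no alternative kept its call (0.0527 to 0.715). In post-polysomal RNA DNA replication genes had a median of -0.27 with 0 of 41 past and 0 adjusted over the list alone (camera adjusted p = 0.0273). That list had an adjusted p = 0.980 with an estimated correlation and 0.0558 without the dimmest genes and 0.0583 with the mean over exon-level probesets, within a range of 0.00880 to 0.980. In total RNA, with 1 array per line, its median was 0.33, opposite in sign to its medians in both fractions. The cause of that conflict was not tested.

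Ribosomal protein genes did not differ between the lines in either fraction by camera (median -0.06 and adjusted p = 0.899 in polysomal RNA, -0.09 and 0.120 in post-polysomal RNA), with 0 of 55 genes past in each. Between the fractions, genes of the MAPK, hypoxia and basal lists stood low in polysomal RNA. These lists were not matched on exon probesets, so RNA size was not separated from their place. Of 21 MAPK output genes, 17 were lower in MSCV cells and 14 in YB-1 cells (17 and 14 adjusted over the list alone), with medians of -1.35 and -1.06 relative to all genes (camera adjusted p = 4.06e-06 and 1.19e-05). Of 32 hypoxia genes, 17 were lower and 2 higher in MSCV cells and 21 lower in YB-1 cells (18 and 2, then 22, adjusted over the list alone), with relative medians of -0.74 and -0.996 (0.000263 and 1.33e-05). Of 25 basal genes, 19 were lower in MSCV cells and 10 in YB-1 cells, each with 1 higher (19 and 12 lower adjusted over the list alone), with relative medians of -1.92 and -0.39 (2.11e-07 and 0.00876). Between the lines, 12 of these 25 genes were lower in polysomal and 18 in post-polysomal RNA of YB-1 cells. Low signal was therefore not separated from the smaller relative difference in YB-1 cells. The call of the basal list in YB-1 cells ended without the dimmest genes (adjusted p = 0.0807) and after quantile normalization (0.0509), with an adjusted p of 0.00899 to 0.556 over all alternatives. With an estimated correlation no list had an adjusted p below 0.439 in MSCV cells or 0.542 in YB-1 cells.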
